A study of Schizosaccharomyces pombe with 40 samples.

How the data were processed

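The series holds 40 samples of Schizosaccharomyces pombe. Of these, 17 are polyA RNA-seq libraries and were used, and 23 are chromatin immunoprecipitation and input samples, which were not analysed here. The RNA libraries were placed in 7 groups from their labels: 3 wild-type, 3 ebp1Δ and 3 eaf1Δ libraries of strain ED666, 2 wild-type and 2 ell1Δ libraries of ED666 with the replicate suffix b (called ED666b), and 2 wild-type and 2 ell1Δ libraries of strain Pem2. The suffix b was read as a separate set, and ell1Δ in ED666 was compared with the wild-type libraries that carry it. Columns were joined to samples by name. The columns of 1 group carry a code that is in no label, and they were given to ebp1Δ because every other column matched another sample.

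The authors deposited 1 table of 7014 lines, in which 1 identifier is repeated, leaving 7013 genes. The column headed cpm in that deposited table was treated as a signal, because each library is a whole number of reads per gene times 1 constant and sums to between 915972 and 1045680 instead of a fixed total. The constant is called the value of 1 read here and the column scaled CPM; 100% of its values came out whole within a tolerance of 0.01. Per the file headers the authors also deposited RPKM values, which equal the same signal divided by a gene length, and these gave the gene lengths used in the length test and nothing else. The authors' log2 fold changes and mean log2 CPM values of 4 comparisons stand in the deposited table, per the file headers. The authors' p-values and adjusted p-values stand beside them in the deposited table and were used only to count and compare calls. Per the submitters' processing notes the tools were Bowtie2 2.2.9, SAMtools 1.3.1, MACS2, TopHat2 2.1.1 and edgeR, and the build was ASM294v2. The read counter, the annotation, the use of strand and the settings are not given in the sources used here. The reference given was a later build, so no coordinates are printed, and it served only for names, biotypes and the order of genes; 6845 of 7013 identifiers matched it.

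Recovered reads per library ran from 6486554 to 9193169 in ED666, from 38150862 to 43374049 in ED666b and from 35337271 to 40796006 in Pem2. The floor of 3 reads was 0.462 scaled CPM at the lowest depth and 0.0692 at the highest. Reads are not independent molecules, so the floor covers counting error only. No pair of replicates agreed within sampling noise.

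The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The design foresaw normalized expression values or counts, and the signal was tested as the former. Genes at 1 scaled CPM or more in at least 2 libraries were kept, which left 6160. A single limma model (limma 3.58.1 in R 4.3.3) of 7 group means was fitted over all 17 libraries to log2(scaled CPM + 1), with trend and robust options off, so that groups of 2 and 3 libraries share 1 estimate of the spread per gene. Residual degrees of freedom were 10 and prior degrees of freedom 2.61. Calls are at an adjusted p of 0.05 after Benjamini-Hochberg adjustment over the genes tested. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The 8 comparisons are the 4 deletions against their own wild type, the difference of the ell1Δ effects, eaf1Δ against ebp1Δ, and the ED666b ell1Δ effect against the eaf1Δ and ebp1Δ effects.

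Of 25 gene lists fixed in advance, 24 were tested by limma camera with a preset correlation of 0.01, adjusted over 96 tests, and again with an estimated correlation; the other list holds the 3 deleted genes. The lists cover RNA polymerase II subunits, elongation factors, core stress response, heat shock chaperones, iron, copper, phosphate, thiamine, nitrogen starvation, mating, meiosis, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial respiration, glycolysis, hexose uptake, flocculins, histones, G1/S genes, sterol, purine and amino acid synthesis, and retrotransposons with subtelomeric genes. The result of 1 more list is not reported here, and the counts of lists and of named genes include it. Called members were counted over all genes and adjusted over the list alone. Agreement between deletions was measured by Pearson's r and Spearman's rho across genes and by two-sided Fisher's exact tests of shared calls, with unchanged groups simulated in 100 draws for the pair that shares controls, whose overlap was counted for calls and for lists of the observed lengths.

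Named genes followed a fixed rule. For each deletion these were the 10 called genes that rose most and the 10 that fell most, without the deleted gene, where every deletion library lay on the same side of every control library and the higher group had a mean of 5 or more. Random placement gives such separation for 10% of genes with 3 libraries against 3 and 33.3% with 2 against 2. The rule adds the 3 deleted genes, up to 4 called members of each list with the smallest p (or up to 2 uncalled members, as values), and the 5 largest called differences each way.

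On simulated data with known changes, using 5 draws of 50 changed genes per fold among 6160, the limma step recovered 96.8%, 93.2%, 92.4% and 92.8% of 2-fold changes and 77.6%, 79.6%, 63.6% and 66.8% of 1.5-fold changes in ebp1Δ, eaf1Δ, ED666b ell1Δ and Pem2 ell1Δ. False calls made up 7.92%, 7.31%, 2.66% and 3.46% of calls. Changed genes were drawn only from those with a mean of 5 or more scaled CPM. Libraries were drawn independently, without the correlation of same-numbered libraries seen in the ell1Δ sets. The rates therefore do not cover lower genes or such correlated libraries.

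Alternatives were pseudocounts of 0.1 and 5, no low-value filter, a filter at 5, quantile normalization, median centring, a replicate block, limma with trend and robust prior, a fit of the compared groups only, all 5 ED666 wild-type libraries as controls, and each library left out in turn. A library was left out only for the comparisons, or pairs of comparisons, that include its group. Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means. In the 4 groups of the ell1Δ comparisons all 12 such pairs had r of 0.424 to 0.709, although with 2 libraries per group the deviations of numbers 1 and 2 mirror each other. The labels give only the numbers, so the fit without the block is reported first. In that fit, leaving out 1 library also leaves the numbers unequal between the compared groups. Such fits do not separate a library from its number. Where leaving out a library leaves 1 library in a group, that library is assumed to vary like the other groups. After the data were seen, edgeR 4.0.16 (quasi-likelihood test on the recovered reads), the list tests with each library left out, the overlaps of calls and the antisense counts with each library left out and with the replicate block, and 2 further comparisons for the length test were added. Tables were built with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.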

Results

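The series asked what the loss of ELL, its partner EAF and a further associated protein, Ebp1, does to transcription in the fission yeast Schizosaccharomyces pombe. ELL is an elongation factor of RNA polymerase II, and EAF is its binding partner. PolyA RNA was sequenced from 17 libraries of cells grown in rich medium to mid log phase. They fall into 7 groups. Strain ED666 gave 3 wild-type, 3 ebp1Δ and 3 eaf1Δ libraries. A further set from ED666, whose replicates carry the suffix b in the labels and which is called ED666b here, gave 2 wild-type and 2 ell1Δ libraries. A strain of the opposite mating type, Pem2, gave 2 wild-type and 2 ell1Δ libraries. The 23 chromatin immunoprecipitation and input samples were not analysed here.

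Depth was 6486554 to 9193169 reads per library in ED666, 38150862 to 43374049 in ED666b and 35337271 to 40796006 in Pem2, as recovered from the deposited values. Levels are given as scaled CPM, the deposited per-library value in which 1 read was worth the same for every gene. A count of 3 reads, taken as the floor, equalled 0.462 scaled CPM in the shallowest library and 0.0692 in the deepest, and it covers counting error only. Replicates of a group correlated at 0.980 or higher across genes on the log2 scale. Wild-type ED666 replicate 3 stood apart from the other 2 of its group. Its 10 most abundant genes took 6.28% of reads, against 8.62% in replicate 1 and 7.86% in replicate 2, and 5.89% to 6.52% in the ebp1Δ libraries. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

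The deleted genes were measured first in every group. In ebp1Δ, ebp1 (SPAC6G9.15c) stood at 9.46 ± 1.04 scaled CPM (SD, n = 3), against 69.1 ± 9.52 (n = 3) in wild type. It was 63.7 ± 3.33 (n = 3) in eaf1Δ, 79.5 ± 6.77 (n = 2) in ED666b wild type, 82.5 ± 4.34 (n = 2) in ED666b ell1Δ, 81.05 ± 5.42 (n = 2) in Pem2 wild type and 84.7 ± 2.99 (n = 2) in Pem2 ell1Δ. The table named the ebp1Δ columns by a code that is in no label, and they were assigned because every other column matched another sample, so this low level is the check of that assignment. In eaf1Δ, eaf1 (SPCC1223.10c) stood at 21.1 ± 1.85 (n = 3), against 49.5 ± 6.78 (n = 3) in wild type. It was 49.7 ± 3.45 (n = 3) in ebp1Δ, 53.7 ± 4.099 (n = 2) and 59.1 ± 1.05 (n = 2) in ED666b wild type and ell1Δ, and 57.1 ± 0.61 (n = 2) and 64.1 ± 0.56 (n = 2) in Pem2 wild type and ell1Δ. For ell1 (SPBP23A10.14c), the ED666b level was 18.6 ± 2.82 (n = 2) in ell1Δ and 79.0 ± 7.84 (n = 2) in wild type, and the Pem2 level was 28.2 ± 4.103 (n = 2) in ell1Δ and 69.9 ± 2.07 (n = 2) in wild type. In ED666 it was 84.6 ± 16.5 in wild type, 84.6 ± 3.27 in ebp1Δ and 83.7 ± 0.0671 in eaf1Δ (n = 3 each).

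By limma with Benjamini-Hochberg adjustment, ebp1 fell by 2.74 on the log2 scale in ebp1Δ (SE 0.10, adjusted p = 8.87e-09) and eaf1 fell by 1.19 in eaf1Δ (SE 0.09, adjusted p = 5.31e-05). In the same limma model, ell1 fell by 2.03 in ED666b (SE 0.15, adjusted p = 2.26e-05) and by 1.29 in Pem2 (SE 0.15, adjusted p = 0.0028). Each deleted gene kept a residual level well above the floor. Which part of each gene was removed is not given in the sources used here, so these residual levels cannot be assigned to a transcript. When the Pem2 fit used only its own 4 libraries, the ell1 call ended (limma adjusted p = 0.138, over its alternatives 0.00125 to 0.138).

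**Figure D1:**
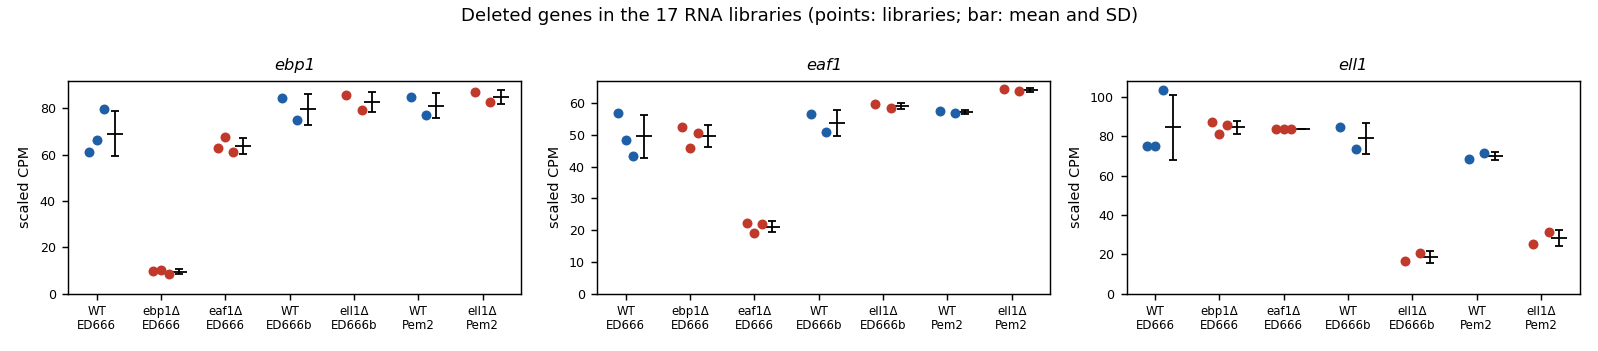
Levels of ebp1, eaf1 and ell1 (scaled CPM) in the 7 groups, with 1 point per library and bars at the group mean with the SD. Each gene was lowest in the libraries that carry its own deletion, with ebp1 at a mean of 9.46 in ebp1Δ and eaf1 at 21.1 in eaf1Δ.

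More genes fell than rose in ebp1Δ. The SPBC460.04c transcript fell from 46.3 ± 3.73 to 4.65 ± 1.94 scaled CPM (n = 3 each), a log2 change of -3.13 (SE 0.34), and SPBC460.05 fell by 2.51 (SE 0.35). The neighbouring coding genes abp2, which encodes an origin-binding protein, and cnp3, which encodes the kinetochore protein CENP-C, fell by 2.57 (SE 0.12) and 2.37 (SE 0.14). The abp2 level was 20.4 ± 1.20 in ebp1Δ and 126 ± 12.5 in wild type, and the cnp3 level was 39.9 ± 2.63 and 213 ± 40.1 (n = 3 each). The noncoding RNA SPNCRNA.1673, which overlaps abp2 on the opposite strand, fell by 3.03 (SE 0.28), and the nearby pair SPNCRNA.782 and SPNCRNA.779 fell by 2.54 (SE 0.19) and 2.47 (SE 0.20). Whether the authors' counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart and such values are uncertain.

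Other genes that fell most in ebp1Δ were the enolase gene eno102 at -3.02 (SE 0.57), rds1 at -2.45 (SE 0.44) and SPAC2H10.01 at -2.41 (SE 0.60). The genes that rose most were SPNCRNA.577 (1.62, SE 0.36), SPNCRNA.1364 (1.11, SE 0.28), SPNCRNA.737 (1.03, SE 0.25), mei4, which encodes a meiotic forkhead transcription factor (0.97, SE 0.20), mug146 (0.94, SE 0.20), SPNCRNA.875 (0.93, SE 0.16), SPAC11D3.18c (0.91, SE 0.22), SPNCRNA.980 (0.89, SE 0.15), mat2-Pc (0.89, SE 0.19) and SPNCRNA.1190 (0.80, SE 0.17). The file names SPNCRNA.577, SPNCRNA.875 and SPNCRNA.980 as antisense to SPBC1652.02, gcv1 and ayr1. The mat2-Pc gene of the silent mating cassette has near-identical copies, so its value is also uncertain. For mei4 the level was 21.5 ± 4.94 in ebp1Δ and 10.4 ± 1.71 in wild type (n = 3 each). Adjusted p-values of these 20 genes ran from 7.99e-08 (abp2) to 0.0467 (SPNCRNA.1364) by limma with Benjamini-Hochberg adjustment.

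Core stress response genes fell as a list in ebp1Δ. Of 20 measured members, 5 fell and 0 rose over all genes tested, and the same numbers passed when adjusted over the list alone. Among them were gpd1, for glycerol-3-phosphate dehydrogenase (-1.69, SE 0.18), obr1 (-1.495, SE 0.17), the catalase gene ctt1 (-1.57, SE 0.31) and the heat shock protein gene hsp9 (-1.75, SE 0.38). The gpd1 level was 576 ± 141 in ebp1Δ and 1837 ± 289 in wild type (n = 3 each). By limma camera the list fell relative to other genes (adjusted p = 8.54e-05), with adjusted p = 0.625 with an estimated correlation. The 16 genes of glycolysis and fermentation fell as a list (camera adjusted p = 1.91e-04; adjusted p = 0.625 with an estimated correlation). Of these, 3 fell (hxk2 at -0.46, SE 0.06; eno102; adh1 at -0.56, SE 0.14) and 1 rose (pdc201 at 0.79, SE 0.13), and 9 fell and 1 rose when adjusted over the list alone. Wild-type replicate 3 stood apart in eno102, at 60.2 scaled CPM against 16.1 and 11.7 in replicates 1 and 2, with 2.21, 0.809 and 3.29 in the ebp1Δ libraries.

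Meiotic genes rose as a list in ebp1Δ, with 19 of 20 measured members at a positive log2 fold change (camera adjusted p = 2.21e-07; adjusted p = 0.616 with an estimated correlation). Over all genes 4 rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell. The 4 were rec25, for a meiotic recombination protein (0.79, SE 0.14), spo6 (0.63, SE 0.13), mei4 and mes1 (0.32, SE 0.08). The mitochondrial respiration list rose by a median of 0.10 over 55 genes (camera adjusted p = 7.15e-04; adjusted p = 0.739 with an estimated correlation), with cyc1, for cytochrome c, its only called member over all genes and when adjusted over the list alone (0.40, SE 0.08). At the preset correlation these 4 list calls held with each library left out in turn and under each other setting, and with an estimated correlation they ended.

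Regrouping the 6 ebp1Δ and wild-type libraries 3 against 3 gave up to 13 called lists, against 7 for the real grouping. Of the 10 splits 6, the real one among them, gave at least 7, so the number does not set ebp1Δ apart. A further 2 list calls in ebp1Δ rested on single libraries. The ribosome biogenesis list rose by a median of 0.14 over 52 genes, with 0 members called by limma over all genes or when adjusted over the list alone (camera adjusted p = 9.67e-06; adjusted p = 0.792 with an estimated correlation). Without wild-type replicate 3 its adjusted p by camera was 0.990, and the range over its alternatives was 1.28e-10 to 0.990. The list of 137 cytosolic ribosomal protein genes was up, with a median of 0.04 and 33 members at a negative log2 fold change, again with 0 members called by limma over all genes or when adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.916 with an estimated correlation). Without wild-type replicate 3 this list turned to a fall (limma camera adjusted p = 0.00889), and its call ended under quantile normalization and without ebp1Δ replicate 1 (limma camera adjusted p = 0.113 without that library, over its alternatives 1.57e-07 to 0.113).

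In lists that were not called as a whole, single members changed in ebp1Δ. The phosphate transporter gene pho84 fell by 2.08 (SE 0.30) and the acid phosphatase gene pho1 fell by 1.93 (SE 0.41). Of 6 phosphate response genes these 2 fell over all genes, and adjusted over the list alone 2 fell and 3 rose. The median of that list was 0.02 while its mean was -0.55 and its test pointed down. Wild-type replicate 3 had pho1 at 219 scaled CPM, against 627 and 564 in replicates 1 and 2. Of 13 nitrogen starvation genes the ammonium transporter gene amt1 rose (0.74, SE 0.14) and put4 fell (-0.55, SE 0.13), and 1 rose and 2 fell when adjusted over the list alone. Of 11 hexose uptake genes rst2 rose (0.32, SE 0.06) and ght8 fell (-0.78, SE 0.19), and 2 rose and 1 fell when adjusted over the list alone. The genes erg1 (-0.40, SE 0.07), erg31 (-0.88, SE 0.17) and hem13 (-0.53, SE 0.12) fell among 23 sterol synthesis genes, where 3 fell when adjusted over the list alone. Of 10 flocculins pfl7 fell (-0.46, SE 0.10), and 1 fell when adjusted over the list alone. Of 10 histone genes the H3 gene hht1 fell (-0.29, SE 0.06), and 1 rose and 3 fell when adjusted over the list alone. Adjusted p-values of these genes lay between 0.00156 (pho84) and 0.039 (put4) by limma with Benjamini-Hochberg adjustment.

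In total 226 of 6160 tested genes passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment in ebp1Δ against wild type, 57 up and 169 down, and 65 of them by 2-fold or more. Quantile normalization put the share that rose at 35.6% instead of 25.2%. The count was 368 without wild-type replicate 3, 134 without ebp1Δ replicate 2, 141 without ebp1Δ replicate 3 and 65 when only these 6 libraries were fitted, and of 46 named genes 21 kept their call with each library left out, among them SPBC460.04c, SPBC460.05, abp2, cnp3, gpd1, obr1, pho84, eno102, rds1 and rec25. Leaving out ebp1Δ replicates 1, 2 and 3 ended 10, 25 and 19 of the named calls, and leaving out wild-type replicates 1, 2 and 3 ended 18, 9 and 5, at adjusted p-values by limma of 0.0502 to 0.179. The put4 call ended without any 1 of the 6 libraries. Among these fits pho1, adh1, ght8 and SPAC2H10.01 kept their call only without wild-type replicate 3. The mei4 call ended without wild-type replicates 1 or 2 or ebp1Δ replicates 2 or 3. Under every alternative 11 of the 46 named genes kept their call, among them SPBC460.04c, SPBC460.05, abp2, cnp3, gpd1, obr1 and pho84. When only the 6 compared libraries were fitted, eno102, rds1 and rec25 lost their call (limma adjusted p = 0.106, 0.0517 and 0.0911).

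In eaf1Δ most genes that rose, 19 of 32, were RNAs named as antisense to a gene. Over all antisense RNAs the median log2 fold change was -0.01, and the use of strand in counting is not known. The RNA SPNCRNA.1211, antisense to SPCC777.06c, rose from 6.13 ± 0.747 to 19.5 ± 0.306 scaled CPM (n = 3 each), a log2 change of 1.53 (SE 0.21). SPNCRNA.1454, antisense to SPBC19C2.10, rose by 1.07 (SE 0.09) and SPNCRNA.1206, antisense to nup211, by 1.05 (SE 0.14). The subtelomeric helicase gene tlh2, whose family has near-identical copies and whose value is uncertain, rose by 1.25 (SE 0.17). The agn1 gene, for a glucanase, fell from 216 ± 14.3 to 144 ± 11.1 (n = 3 each), a log2 change of -0.58 (SE 0.08).

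The other RNAs that rose most in eaf1Δ were SPNCRNA.1627, antisense to rng9 (1.22, SE 0.20), SPNCRNA.1020 (1.10, SE 0.19), SPNCRNA.560 (1.08, SE 0.16), SPNCRNA.707 (0.995, SE 0.16), SPNCRNA.1487 (0.91, SE 0.18) and SPNCRNA.1190 (0.91, SE 0.17). The subtelomeric gene SPAC750.01 fell by 2.53 (SE 0.24), from 13.96 ± 3.37 to 1.57 ± 0.454 (n = 3 each), and its value is uncertain because subtelomeric genes have close copies. The genes ftm4 and SPAC750.06c, named here after their values were seen, were also low in these eaf1Δ libraries. Whether such falls follow from the loss of eaf1 itself was not tested. The neighbours abp2 and cnp3 fell here too, by 1.01 (SE 0.12) and 0.98 (SE 0.14). Falls were also called for SPNCRNA.716 (-0.71, SE 0.12), rib7 (-0.71, SE 0.14), SPNCRNA.844 (-0.52, SE 0.10), rng9 (-0.50, SE 0.08), cfh4 (-0.45, SE 0.08) and SPNCRNA.669 (-0.40, SE 0.07). These 20 genes, agn1 and tlh2 included, had adjusted p-values of 6.11e-05 (SPNCRNA.1454) to 0.0374 (SPNCRNA.1487 and rib7) by limma with Benjamini-Hochberg adjustment.

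Of 10 histone genes in eaf1Δ the H4 gene hhf3 (-0.37, SE 0.07) and hht1 (-0.28, SE 0.06) fell, 3 fell when adjusted over the list alone, and the list fell by a median of 0.11 (camera adjusted p = 0.00131; adjusted p = 0.625 with an estimated correlation). The list of 5 tested retrotransposon and subtelomere genes was up (camera adjusted p = 7.46e-04, and 0.598 with an estimated correlation). Over all genes 1 of them, tlh2, was called, and 2 when adjusted over the list alone. Of 15 genes on this list only these 5 passed the low-value filter. Copies of retrotransposons and of tlh2 may share reads, so their values are uncertain. The respiration list decreased by 0.11 in the median of its 55 genes (camera adjusted p = 3.67e-04; adjusted p = 0.739 with an estimated correlation). The list of 20 meiotic genes was up, with 18 members at a positive log2 fold change and a median of 0.40 (camera adjusted p = 1.66e-04; adjusted p = 0.725 with an estimated correlation). Neither of those 2 lists had a member called by limma over all genes or when adjusted over the list alone, and mug9, the meiotic gene with the smallest p, had a log2 fold change of 1.24 (SE 0.37, limma adjusted p = 0.149). At the preset correlation these 4 list calls held with each library left out in turn and under each other setting, and with an estimated correlation they ended. Regrouping these libraries 3 against 3 gave up to 8 called lists, against 11 for the real grouping.

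A further 6 list calls in eaf1Δ depended on single libraries, and each of them ended without wild-type replicate 3. They were ribosome biogenesis up (camera adjusted p = 2.68e-05; adjusted p = 0.792 with an estimated correlation), amino acid synthesis up (camera adjusted p = 1.54e-04; adjusted p = 0.763 with an estimated correlation) and heat shock chaperones up (camera adjusted p = 0.0114; adjusted p = 0.739 with an estimated correlation). Purine synthesis was up (camera adjusted p = 0.0141; adjusted p = 0.792 with an estimated correlation), mating and pheromone genes were down (camera adjusted p = 0.0154; adjusted p = 0.725 with an estimated correlation) and flocculins were up (camera adjusted p = 0.0493; adjusted p = 0.725 with an estimated correlation). By limma 0 members of these 6 lists passed over all genes; adjusted over the list alone, 3 of 10 flocculins rose and 1 of 19 mating genes fell. Without wild-type replicate 3 the ribosome biogenesis and purine lists turned in direction, with camera adjusted p-values of 0.419 and 0.508, and those of the 4 other lists rose above the threshold, up to 0.990 for amino acid synthesis (over its alternatives 4.70e-08 to 0.990). The purine call also ended without eaf1Δ replicate 2, the heat shock call without eaf1Δ replicate 1, and the flocculin call without wild-type replicate 2 and eaf1Δ replicates 2 and 3. Quantile normalization ended the heat shock call, and a pseudocount of 0.1 or median centring the flocculin call.

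In eaf1Δ against wild type 52 of 6160 genes passed by limma with Benjamini-Hochberg adjustment, 32 up and 20 down, and 16 of them by 2-fold or more. The count was 24 without eaf1Δ replicate 2, 21 without eaf1Δ replicate 3, 11 when only these 6 libraries were fitted, 27 by edgeR on the recovered reads and 121 against all 5 ED666 and ED666b wild-type libraries. Of 24 named genes, 10 kept their call with each library left out, namely SPNCRNA.1211, tlh2, SPNCRNA.560, SPNCRNA.1454, SPNCRNA.1206, SPAC750.01, abp2, cnp3, agn1 and eaf1. Under every alternative 5 kept it, namely SPNCRNA.1211, SPNCRNA.1454, SPNCRNA.1206, SPAC750.01 and eaf1. Leaving out eaf1Δ replicates 1, 2 and 3 ended 3, 13 and 13 calls and wild-type replicates 1, 2 and 3 ended 5, 2 and 6, at adjusted p-values by limma of 0.0508 to 0.151.

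In ED666b ell1Δ most genes that rose, 18 of 25, were again RNAs named as antisense. SPNCRNA.1211 rose from 5.36 ± 0.238 to 24.4 ± 3.35 scaled CPM (n = 2 each), a log2 change of 1.99 (SE 0.26), and SPNCRNA.1273, antisense to SPCC1919.05, rose by 1.76 (SE 0.28). The agn1 level fell from 202 ± 14.04 to 138 ± 3.59 (n = 2 each), by 0.54 on the log2 scale (SE 0.10). The largest falls were in rpn501, for the proteasome subunit Rpn5 (-4.71, SE 0.12), and the adjacent cox1101, for a cytochrome c oxidase assembly protein (-2.41, SE 0.19). Each of those 2 has a near-identical second copy, rpn502 and cox1102, so both values are uncertain.

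The remaining named rises in ED666b were SPNCRNA.1627 (1.64, SE 0.24), SPNCRNA.632, antisense to tra2 (1.51, SE 0.26), SPNCRNA.560 (1.25, SE 0.20), tlh2 (1.25, SE 0.20), SPNCRNA.707 (1.24, SE 0.20), SPNCRNA.1020 (1.24, SE 0.23), SPNCRNA.1206 (1.21, SE 0.17) and SPNCRNA.561, antisense to pkl1 (1.19, SE 0.16). Besides agn1, the named falls were adg3 (-0.51, SE 0.10), cfh4 (-0.51, SE 0.10) and mid2 (-0.40, SE 0.08). Adjusted p-values ran from 1.05e-10 (rpn501) to 0.0432 (cfh4) by limma with Benjamini-Hochberg adjustment.

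In ED666b the 5 retrotransposon and subtelomere genes tested rose as a list by a median of 0.77 (camera adjusted p = 4.15e-07, and 0.225 with an estimated correlation). Over all genes tlh2 rose, and 4 rose when adjusted over the list alone. Copies of retrotransposons and of tlh2 may share reads, so these need not be 4 separate rises. Heat shock chaperone genes rose as a list by a median of 0.33 over 15 genes (camera adjusted p = 0.0019; adjusted p = 0.730 with an estimated correlation), with 0 members called by limma over all genes or when adjusted over the list alone. The member with the smallest p, hsp10, had a log2 fold change of 0.34 (SE 0.11, limma adjusted p = 0.388). At the preset correlation these 2 list calls held with each library left out in turn and under each other setting, and with an estimated correlation they ended.

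A further 6 list calls in ED666b ended without wild-type replicate 1b, at camera adjusted p-values up to 0.881 for mitochondrial respiration (over its alternatives 4.58e-14 to 0.881). That list was down (camera adjusted p = 6.49e-05; adjusted p = 0.730 with an estimated correlation), with cox1101 its only called member over all genes and when adjusted over the list alone. The phosphate list was down (camera adjusted p = 0.00432; adjusted p = 0.332 with an estimated correlation), with 0 members over all genes and 2 down when adjusted over the list alone; pho1 had a log2 fold change of -1.91 (SE 0.50) and pho84 of -1.20 (SE 0.37). The G1/S list was down (camera adjusted p = 0.00236; adjusted p = 0.607 with an estimated correlation), with 0 members over all genes and 1 down when adjusted over the list alone. Histones were down (camera adjusted p = 0.00674; adjusted p = 0.725 with an estimated correlation), cytosolic ribosomal proteins up (camera adjusted p = 0.0328; adjusted p = 0.916 with an estimated correlation) and iron acquisition up (camera adjusted p = 0.0443; adjusted p = 0.739 with an estimated correlation), each with 0 members by limma over all genes or when adjusted over the list alone. Histones also ended without ell1Δ replicate 1b, ribosomal proteins without ell1Δ replicate 2b, and iron acquisition without wild-type replicate 2b and ell1Δ replicate 2b. Quantile normalization ended the histone call, fitting only the compared groups or with the replicate number as a block ended the ribosomal protein call (camera adjusted p over its alternatives 3.29e-04 to 0.702), and median centring or no low-value filter ended the iron call.

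In ell1Δ against wild type in ED666b 32 of 6160 genes passed by limma with Benjamini-Hochberg adjustment, 25 up and 7 down, and 21 of them by 2-fold or more. The ED666 libraries enter this comparison only through the spread that all groups share. Deleted genes aside, 46 genes rose and 15 fell without ED666 wild-type replicate 3, and 19 rose and 2 fell without ED666 wild-type replicate 2. Leaving out wild-type replicate 1b, wild-type 2b, ell1Δ 1b or ell1Δ 2b left 8, 5, 6 and 7 genes, with the lone library assumed to vary like the other groups, and 50 genes passed against all 5 ED666 and ED666b wild-type libraries. Of 17 named genes rpn501, cox1101 and ell1 kept their call with each library left out. In the same order these left-out libraries ended 13, 14, 12 and 14 of the named calls, at adjusted p-values by limma of 0.0561 to 0.497, and agn1, cfh4, mid2, adg3, SPNCRNA.1206, SPNCRNA.1273, SPNCRNA.1627, SPNCRNA.632, SPNCRNA.560, SPNCRNA.707, SPNCRNA.1020 and SPNCRNA.561 each ended without any 1 of the 4 libraries. With the replicate number as a block agn1 and cfh4 also ended (limma adjusted p = 0.0600 and 0.0981, over their alternatives 0.00299 to 0.314 and 0.00489 to 0.451), while pho84 passed there and under no other alternative (limma adjusted p = 0.00503, against 0.388 without the block).

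In Pem2 the ell1Δ libraries had higher levels of the same kind of RNA. SPNCRNA.1273 rose from 3.61 ± 1.17 to 21.1 ± 5.81 scaled CPM (n = 2 each), a log2 change of 2.26 (SE 0.28). SPNCRNA.1211 rose by 1.79 (SE 0.26), SPNCRNA.1206 by 1.57 (SE 0.17), SPNCRNA.1613, antisense to SPBC887.02, by 1.53 (SE 0.23), SPNCRNA.1289, antisense to ubp12, by 1.503 (SE 0.26), SPNCRNA.561 by 1.15 (SE 0.16) and SPNCRNA.1454 by 1.01 (SE 0.11). The subtelomeric gene ftm4 (SPAC750.05c) rose by 1.53 (SE 0.20). The agn1 level fell from 196 ± 16.1 to 122.7 ± 4.25 (n = 2 each), a log2 change of -0.67 (SE 0.10), and SPBPB10D8.01, a gene with close copies whose value is uncertain, and SPNCRNA.1306 fell by 1.11 (SE 0.19) and 0.58 (SE 0.10). Adjusted p-values of these 11 genes ran from 0.0019 (SPNCRNA.1206 and SPNCRNA.1454) to 0.0313 (SPNCRNA.1289) by limma with Benjamini-Hochberg adjustment.

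Histone genes fell as a list in Pem2 by a median of 0.17 over 10 genes (camera adjusted p = 2.63e-07; adjusted p = 0.313 with an estimated correlation), with 0 members called by limma over all genes and 3 down when adjusted over the list alone. The log2 fold change was -0.29 (SE 0.07) for hht1 and -0.36 (SE 0.09) for hhf3, with limma adjusted p-values of 0.167 and 0.178. The list of 137 cytosolic ribosomal protein genes was down, with a median of -0.08 (camera adjusted p = 2.78e-10; adjusted p = 0.739 with an estimated correlation), with 0 members called by limma over all genes or when adjusted over the list alone. At the preset correlation these 2 list calls held with each library left out in turn and under each other setting, and with an estimated correlation they ended.

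A further 6 list calls in Pem2 ended without wild-type replicate 1, at camera adjusted p-values up to 0.824 for mating genes (over its alternatives 5.83e-04 to 0.824). They were mitochondrial respiration down (camera adjusted p = 1.52e-05; adjusted p = 0.725 with an estimated correlation), heat shock chaperones up (camera adjusted p = 0.00116; adjusted p = 0.725 with an estimated correlation) and core stress response up (camera adjusted p = 0.0067; adjusted p = 0.739 with an estimated correlation). The retrotransposon and subtelomere list was up (camera adjusted p = 0.00674; adjusted p = 0.625 with an estimated correlation), the phosphate list down (camera adjusted p = 0.0467; adjusted p = 0.616 with an estimated correlation) and mating genes down (camera adjusted p = 0.0493; adjusted p = 0.739 with an estimated correlation). By limma 0 members of these 6 lists passed over all genes or when adjusted over the list alone, and the log2 fold change was -1.53 (SE 0.50) for pho1 and -0.88 (SE 0.37) for pho84. All but the heat shock call also ended without ell1Δ replicate 2, and the mating call also without ell1Δ replicate 1. Fitting only the compared groups, a pseudocount of 0.1, no low-value filter or a filter at 5 each ended the phosphate and mating calls, quantile normalization the phosphate call, and no low-value filter the subtelomere call.

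In ell1Δ against wild type in Pem2 15 of 6160 genes passed by limma with Benjamini-Hochberg adjustment, 11 up and 4 down, and 11 of them by 2-fold or more. The count was 3 without wild-type replicate 1 or ell1Δ replicate 2, 9 without ell1Δ replicate 1, 23 with a pseudocount of 5, 40 by edgeR on the recovered reads, and 0 by limma when only the 4 Pem2 libraries were fitted, where 530 genes had an unadjusted p under 0.05. SPNCRNA.1206, SPNCRNA.1454 and ell1 kept their call with each of the 4 libraries left out, and of the other 9 named genes 9 ended without wild-type replicate 1, 4 without wild-type replicate 2, 4 without ell1Δ replicate 1 and 9 without ell1Δ replicate 2, at adjusted p-values by limma of 0.0619 to 0.551. Among these agn1, SPBPB10D8.01 and SPNCRNA.1306 ended without any 1 of the 4 libraries (for agn1 over its alternatives 0.00231 to 0.167). With the replicate number as a block 28 genes passed, SPNCRNA.1289 and SPNCRNA.1306 did not (limma adjusted p = 0.0625 and 0.0572, over their alternatives 0.00617 to 0.551 and 0.0222 to 0.421), and pho84 did, there and under no other alternative (limma adjusted p = 0.0325).

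Across these comparisons the genes that rose were rich in RNAs named as antisense to a gene. Such RNAs made up 9.23% of 6157 tested genes other than the deleted ones. They made up 19 of 32 genes that rose in eaf1Δ (odds ratio 14.8), 18 of 25 in ED666b ell1Δ (odds ratio 26.1) and 10 of 11 in Pem2 ell1Δ (odds ratio 100). In ebp1Δ the share was 13 of 57 among rises (odds ratio 2.95) and 37 of 168 among falls (odds ratio 2.90). Random lists matched on mean level to the rises had median shares above 9.23%. These were 25% for eaf1Δ, 28% for ED666b ell1Δ and 36.4% for Pem2 ell1Δ. The odds ratios and exact tests do not allow for level. No matched lists were drawn for ebp1Δ, so its shares were set only against all tested genes. Fisher's exact test, two-sided and adjusted over 16 such tests, gave p = 9.58e-12, 3.78e-13 and 1.12e-09 for the rises in eaf1Δ, ED666b ell1Δ and Pem2 ell1Δ, and 0.00266 and 7.97e-07 for rises and falls in ebp1Δ. Taken over all antisense RNAs the median log2 fold change was -0.01 in eaf1Δ, 0.11 in ED666b ell1Δ and 0.06 in Pem2 ell1Δ. An antisense RNA that rose and its sense gene gave 47 values over the 3 comparisons, from 30 distinct pairs, with a median log2 fold change of 0.03 for the sense genes and 1.08 for the antisense RNAs. This enrichment was chosen after the fold changes had been seen. The antisense counts were also taken with each library left out, with unadjusted p-values from Fisher's exact test. In ED666b ell1Δ they were 3 of 3 rises without wild-type replicate 1b or ell1Δ 2b (exact p = 7.81e-04), 2 of 2 without wild-type 2b (p = 0.00850) and 2 of 3 without ell1Δ 1b (p = 0.0239). In Pem2 ell1Δ they were 2 of 2 without wild-type replicate 1 or ell1Δ 2 (exact p = 0.00850), 7 of 8 without ell1Δ 1, 10 of 15 without wild-type 2 (odds ratio 19.99), and 16 of 22 with the replicate number as a block (odds ratio 26.9). In eaf1Δ they were 15 of 41 without wild-type replicate 1 (odds ratio 5.80), 30 of 48 without wild-type 3, 11 of 14 without eaf1Δ 2 (odds ratio 36.7) and 8 of 11 without eaf1Δ 3 (odds ratio 26.6). In ebp1Δ the rises gave 8 of 58 without wild-type replicate 1 (exact p = 0.248), 32 of 143 without wild-type 3 and 5 of 24 without ebp1Δ 2 (p = 0.0641), and the falls 23 of 110 without ebp1Δ 3 (p = 1.55e-04) and 33 of 109 without ebp1Δ 2 (odds ratio 4.47).

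**Figure D2:**
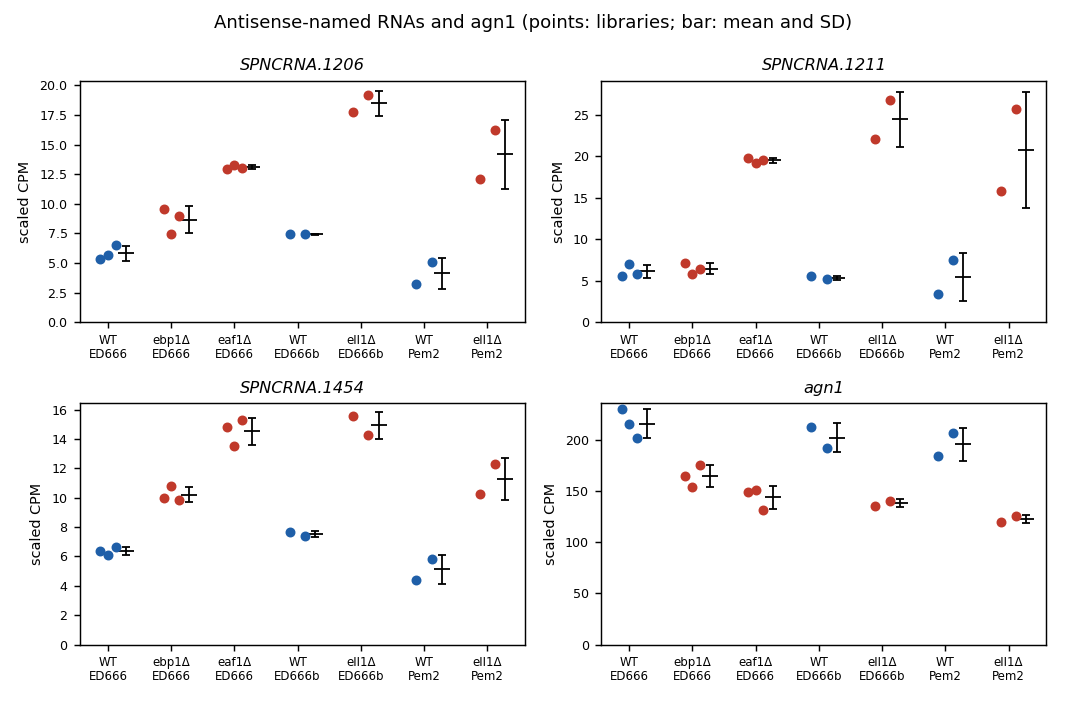
Levels (scaled CPM) of the antisense RNAs SPNCRNA.1206, SPNCRNA.1211 and SPNCRNA.1454 and of agn1 in the 7 groups, with 1 point per library and bars at each group mean with the SD. In Pem2, SPNCRNA.1206 lay at a mean of 4.15 in wild type and 14.2 in ell1Δ, while agn1 lay at 196 and 122.7.

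How far the deletions acted alike was measured by the correlation of log2 fold changes across 6157 genes, which are not independent replicates, and by the overlap of called genes in 6 pairs of comparisons and 2 directions. All comparisons use the same estimate of the spread per gene, so a gene with a low estimate passes more easily in each. Calls are thus not independent even without a shared library, and the exact tests of all 12 overlaps do not allow for this. The eaf1Δ and ED666b ell1Δ effects, which share no library, correlated at r = 0.487 (rho = 0.339). Both raised 13 genes, where independent lists would share 0.130, and lowered agn1, cfh4 and mid2, where 0.0185 would be shared (Fisher's exact test adjusted over the 12 overlaps, p = 7.23e-24 and 9.91e-07). The 13 included tlh2, SPNCRNA.1206, SPNCRNA.1211, SPNCRNA.1454, SPNCRNA.1627, SPNCRNA.560 and SPNCRNA.707. The eaf1Δ and Pem2 ell1Δ effects correlated at r = 0.320 (rho = 0.207) and shared 4 rises, SPNCRNA.1206, SPNCRNA.1211, SPNCRNA.1454 and SPNCRNA.983 (0.0572 for independent lists, Fisher's exact adjusted p = 4.64e-07), and the fall of agn1 (Fisher's exact adjusted p = 0.0111). Those 5 genes were called in all 3 comparisons. With a library left out, r ran from 0.399 to 0.554 for eaf1Δ and ED666b ell1Δ. For eaf1Δ and Pem2 ell1Δ it ran from 0.219, without ED666 wild-type replicate 2, to 0.434. SPNCRNA.983 was named here after its calls were seen. With ED666b the shared rises numbered 3, 1, 3 and 2 without wild-type 1b, wild-type 2b, ell1Δ 1b and ell1Δ 2b, 8, 8 and 6 without eaf1Δ replicates 1, 2 and 3, and 25 without ED666 wild-type 3. The falls of agn1, cfh4 and mid2 were not shared without any 1 of the 4 ED666b libraries or without ED666 wild-type 2, and 1 of them was shared without ED666 wild-type 1, eaf1Δ 2 or eaf1Δ 3. Without ED666b wild-type 1b SPCC757.02c, named here after its calls were seen, was shared instead. With Pem2 the shared rises numbered 2 without Pem2 wild-type 1 or ell1Δ 2, 9 without Pem2 wild-type 2 and 16 without ED666 wild-type 3. The fall of agn1 was not shared without any 1 of the 4 Pem2 libraries, and 2 falls were shared without ED666 wild-type 3. With the replicate number as a block the shared rises were 22 with ED666b, 12 of the 13 among them, and 14 with Pem2, all 4 among them. The shared falls were then mid2, pho84, ecl3 and SPBC409.08 with ED666b, without agn1 and cfh4, and agn1, pho84 and ecl3 with Pem2. SPBC409.08 and ecl3 were named after their calls were seen.

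The 2 ell1Δ effects correlated at r = 0.610 (rho = 0.307) and shared 8 rises, where independent lists would share 0.0447 (Fisher's exact test, adjusted p = 2.08e-17), and the fall of agn1 (Fisher's exact adjusted p = 0.00389). Without Pem2 wild-type replicate 1 this correlation was 0.450. The ebp1Δ effect correlated with those of ell1Δ at r = 0.150 in ED666b and 0.151 in Pem2 (rho = 0.0768 and 0.0637). Without ED666b wild-type replicate 2b the first was 0.0977, and the second was 0.0974 without ED666 wild-type replicate 2 and 0.0830 without Pem2 wild-type replicate 2. With ED666b it shared 2 rises, SPNCRNA.1190 and SPNCRNA.1454 (0.231 for independent lists), and the falls of agn1, cfh4 and mid2 (0.164), with Fisher's exact adjusted p = 0.0240 and 5.64e-04. With Pem2 it shared the rise of SPNCRNA.1454 (Fisher's exact adjusted p = 0.0973) and the falls of agn1, SPBPB10D8.01 and SPNCRNA.1306 (adjusted p = 3.42e-05 by the same exact test). Each of the falls shared with an ell1Δ comparison ended without any 1 of its 4 libraries. The 2 ell1Δ comparisons shared 3 rises without ED666b wild-type 1b, 2 without wild-type 2b, ell1Δ 1b or ell1Δ 2b, 2 without Pem2 wild-type 1 or ell1Δ 2, and 16 with the replicate number as a block, where the 2 shared falls were pho84 and ecl3, the latter named here after its calls were seen, and not agn1. The ebp1Δ and ED666b rises shared were 0 without wild-type 2b or ell1Δ 1b, 1 without wild-type 1b, ell1Δ 2b, ED666 wild-type 1 or ebp1Δ 2 or 3, 4 without ebp1Δ 1 and 10 without ED666 wild-type 3. Their shared falls were 0 without ED666 wild-type 1 or 2, ebp1Δ 2, wild-type 2b or either ell1Δ library, 1 without ebp1Δ 1 (agn1) or wild-type 1b (SPCC757.02c), and 5 without ED666 wild-type 3. The ebp1Δ and Pem2 rises shared were 2 without ED666 wild-type 2, ebp1Δ 1 or 3 or Pem2 wild-type 1, 4 without Pem2 wild-type 2 and 8 without ED666 wild-type 3. Their shared falls were 1 without ED666 wild-type 2, 7 without wild-type 3 and 0 without any 1 of the 4 Pem2 libraries. With the replicate number as a block ebp1Δ shared 6 rises with ED666b, SPNCRNA.1190 and SPNCRNA.1454 among them, and the falls of mid2, pho84, ecl3 and SPBC409.08, without agn1 and cfh4. With Pem2 it then shared 4 rises, SPNCRNA.1454 among them, and the falls of agn1, SPBPB10D8.01, pho84, ecl3 and SPNCRNA.293, the last named after its calls were seen, without SPNCRNA.1306.

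The ebp1Δ and eaf1Δ effects share their 3 wild-type libraries. They correlated at r = 0.519 (rho = 0.534), and unchanged groups simulated against the same controls gave a mean r of 0.505 (0.409 to 0.587 in 100 draws). The covariance of the fold changes was 0.0388 against a simulated 0.0115, a difference of 0.0274. They shared 9 rises and 9 falls, where independent lists would share 0.296 and 0.518, and the falls included abp2, cnp3, agn1, cfh4, mid2, hht1 and rng9. Unchanged groups simulated against shared controls had at most 2 calls in a direction and shared a mean of 0.01 rises and 0 falls. Their lists of the observed lengths (57 and 32 rises, 168 and 19 falls), filled in order of p, shared a mean of 7.17 rises (2 to 12 in 100 draws) and 8.09 falls (3 to 14), and the observed 9 and 9 lay within these ranges. Fisher's exact test, which takes the lists as independent, adjusted over the 12 overlaps, gave p = 2.46e-11 for rises and 1.49e-09 for falls. Shared rises numbered 21 without wild-type replicate 3, 4 and 3 without eaf1Δ 2 and 3, and 2 without ebp1Δ 2, and shared falls 14 without wild-type 2, 17 and 4 without eaf1Δ 1 and 2, and 4 without ebp1Δ 2. With 3 controls no split leaves 2 for each effect, so part of the excess over independent lists may come from the shared libraries. The simulation leaves out the effects and the independent lists the shared controls, so neither excess measures a shared effect.

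**Figure D3:**
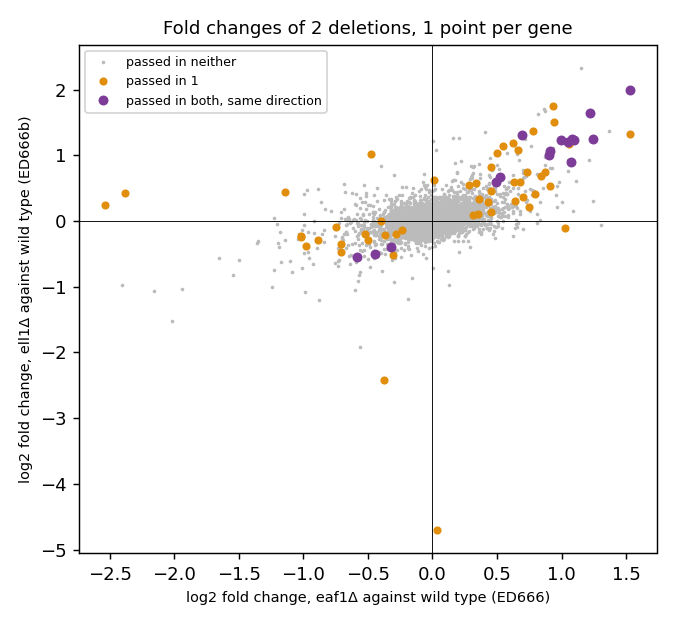
Log2 fold change in ell1Δ (ED666b) against log2 fold change in eaf1Δ (ED666) for each tested gene other than the deleted ones, with the genes called in both in the same direction drawn apart. Across genes r was 0.487, and the 13 genes called up in both lie in the upper right.

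Testing the difference of effects directly, 183 of 6160 genes differed between eaf1Δ and ebp1Δ by limma with Benjamini-Hochberg adjustment, 145 higher in eaf1Δ and 38 lower. The largest, apart from the deleted genes, were SPBC460.04c (2.69, SE 0.34), SPBC23G7.10c (2.55, SE 0.40), SPAC27D7.09c (2.42, SE 0.44) and SPNCRNA.687 (2.40, SE 0.41), higher in eaf1Δ, and the hexose transporter gene ght5 (-3.49, SE 0.67), SPAC750.01 (-1.76, SE 0.24), mat2-Pc (-1.49, SE 0.19) and the phospholipase gene plb1 (-1.15, SE 0.23), lower in eaf1Δ. The deleted genes themselves gave 2.63 (SE 0.10) for ebp1 and -1.20 (SE 0.09) for eaf1. Adjusted p-values of these 10 genes ran from 1.45e-08 to 0.0169 by the same limma test. Levels of ght5 were 1089, 975 and 1031 in the ebp1Δ libraries, 123.4, 77.9 and 77.0 in the eaf1Δ libraries and 129, 70.8 and 948 in wild-type replicates 1, 2 and 3. Levels of plb1 were 2660, 2118 and 2559 in the ebp1Δ libraries and 1628, 1293 and 2766 in the wild-type replicates. Quantile normalization put the share higher in eaf1Δ at 67.7% instead of 79.2%, and the count was 105 and 116 without eaf1Δ replicates 1 and 2, 114 and 103 without ebp1Δ replicates 2 and 3, and 323 when only these 6 libraries were fitted. Among the 10 genes, ght5 lost its call without eaf1Δ replicates 2 or 3 or ebp1Δ replicate 3 (limma adjusted p = 0.0530, 0.0521 and 0.0501), and plb1 without those or ebp1Δ replicate 1 (limma adjusted p of 0.0535 to 0.0755), and no other did.

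Between the ell1Δ effect in ED666b and the eaf1Δ effect 8 genes differed by limma with Benjamini-Hochberg adjustment, 5 higher and 3 lower in ell1Δ. They included ftm4 (2.81, SE 0.26), SPAC750.01 (2.77, SE 0.37), rpn501 (-4.75, SE 0.16), cox1101 (-2.04, SE 0.25) and the deleted genes eaf1 (1.32, SE 0.15) and ell1 (-2.03, SE 0.19). Both ftm4 and SPAC750.01 were low in the eaf1Δ libraries, and whether this follows from the loss of eaf1 was not tested. The SPAC750.01 call ended without ell1Δ replicate 2b (limma adjusted p = 0.0512, over its alternatives 1.98e-05 to 0.0512). The cox1101 call ended against all 5 ED666 and ED666b wild-type libraries (limma adjusted p = 0.0705, over its alternatives 6.59e-04 to 0.0705). The count was 18 against those 5 wild-type libraries, which come from 2 sets of different depth. Neither this count nor the correlation shows that the remaining genes acted alike.

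Between the ell1Δ effect in ED666b and the ebp1Δ effect 44 genes differed by the same limma test, 40 higher and 4 lower in ell1Δ. SPNCRNA.687 (3.22, SE 0.65), SPNCRNA.1673 (2.99, SE 0.44), SPBC460.04c (2.95, SE 0.54), ebp1 (2.79, SE 0.16) and SPNCRNA.782 (2.72, SE 0.31) were higher, and rpn501 (-4.79, SE 0.16), cox1101 (-2.31, SE 0.25), ell1 (-2.05, SE 0.19) and the adenine nucleotide carrier gene anc1 (-0.71, SE 0.13) lower. The count was 71 without ED666 wild-type replicate 3, 22 without ED666b wild-type replicate 1b or ell1Δ replicate 2b, 19 when only the compared groups were fitted and 949 against all 5 wild-type libraries. Of the 9 genes, SPNCRNA.687 lost its call without any 1 of the ebp1Δ, ED666b wild-type or ED666b ell1Δ libraries, SPBC460.04c without ED666 wild-type replicate 1, ED666b wild-type replicate 1b or ell1Δ replicate 2b, and anc1 without ebp1Δ replicate 2 or any 1 of the ED666b libraries, at adjusted p-values by limma of 0.0521 to 0.232. Those 3 and SPNCRNA.1673 also lost it when only the compared groups were fitted (limma adjusted p = 0.0618 for SPNCRNA.1673, over its alternatives 4.67e-05 to 0.0618).

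Whether the ell1 deletion acted alike in both backgrounds was tested as the difference of its effects. By limma with Benjamini-Hochberg adjustment 2 genes differed, rpn501 (-4.56, SE 0.17, adjusted p = 1.16e-08) and cox1101 (-2.38, SE 0.27, adjusted p = 0.00274). Of 6160 genes, 62 had an unadjusted limma p under 0.05, a share well below 0.05, so the test was conservative here. These 2 calls do not show that the remaining genes acted alike in both backgrounds. The rpn501 level was 42.2 ± 1.59 in ED666b wild type and 0.659 ± 0.230 in ED666b ell1Δ, but 0.728 ± 0.231 in Pem2 wild type and 0.556 ± 0.0112 in Pem2 ell1Δ (n = 2 each). The summed level of rpn501 and rpn502 was 131 ± 6.75 in ED666b wild type and 138 ± 2.55 in ell1Δ (n = 2 each). The cox1101 level was 6.08 ± 0.587 in ED666b wild type, 0.330 ± 0.168 in ED666b ell1Δ, 6.03 ± 0.169 in Pem2 wild type and 5.89 ± 0.398 in Pem2 ell1Δ (n = 2 each), and its sum with cox1102 was 11.8 ± 0.630 in ED666b wild type and 9.59 ± 0.216 in ell1Δ (n = 2 each). Both calls held with each of the 8 libraries left out.

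**Figure D4:**
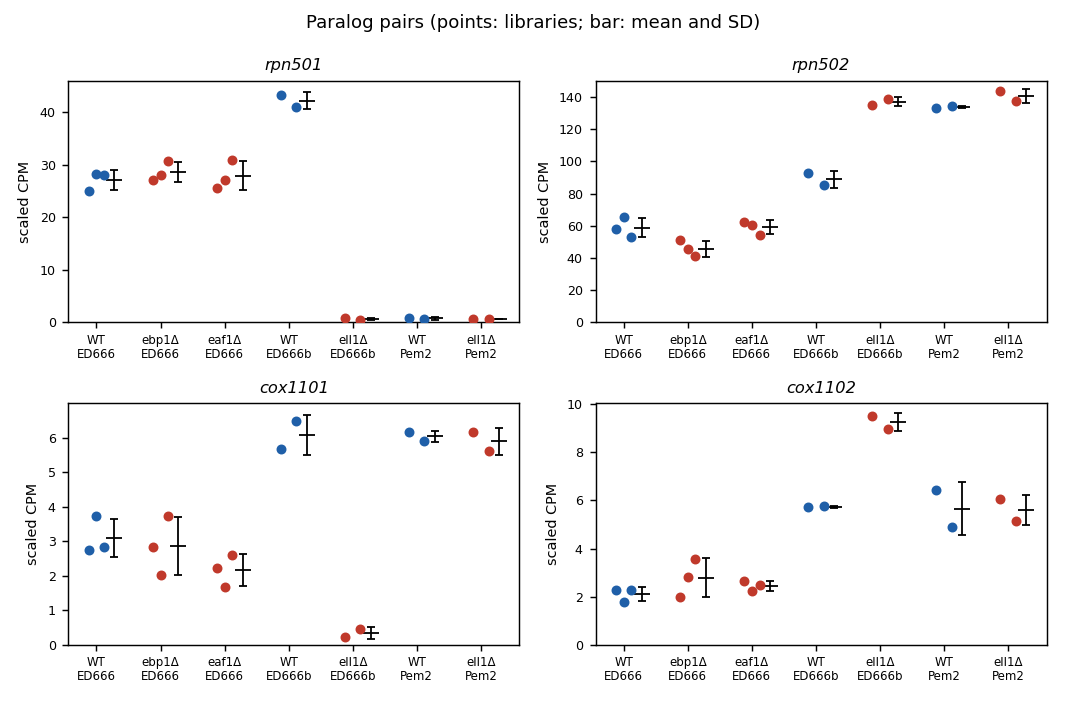
Levels (scaled CPM) of rpn501 and rpn502 and of cox1101 and cox1102 in the 7 groups, with 1 point per library and bars at each group mean with the SD. The rpn501 mean was 42.2 in ED666b wild type and under 1 in ED666b ell1Δ and in both Pem2 groups, where rpn502 lay higher.

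Of 24 lists tested in 4 comparisons, 7 were called in no comparison. The smallest camera adjusted p was 0.391 for RNA polymerase II subunits, 0.0816 for elongation factors, 0.219 for copper uptake, 0.267 for thiamine response, 0.286 for nitrogen starvation, 0.0843 for hexose uptake and 0.0955 for sterol synthesis. With an estimated correlation camera called 0 lists in each comparison, against 7, 11, 9 and 9 with the preset one in ebp1Δ, eaf1Δ, ED666b ell1Δ and Pem2 ell1Δ. At the preset correlation 15 of those 36 calls held under every other setting and left-out library. In 12 of 96 tests by limma camera the direction of the test differed in sign from the list's median or mean, and 0 of these 12 were called (smallest camera adjusted p = 0.789).

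The authors' deposited table called 227 genes in ebp1Δ, 90 in eaf1Δ, 111 in ED666b ell1Δ and 93 in Pem2 ell1Δ at an adjusted p under 0.05. Of these calls in the authors' deposited table, 150, 34, 32 and 15 were also called here, where 226, 52, 32 and 15 passed. Log2 fold changes in the authors' deposited table correlated across genes with those computed here at 0.941, 0.926, 0.919 and 0.953.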

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

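The tests of summed copies and of wild-type levels for rpn501 and cox1101 were chosen only after their levels had been seen. The ell1 deletion effect differed between ED666b and Pem2 in 2 genes by limma's test of the difference, rpn501 (log2 difference -4.56) and its neighbour cox1101 (-2.38), both lower in ED666b.

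The log2 ratio of the summed rpn501 and rpn502 means, ell1Δ over wild type in ED666b, was 0.071, so reads missing from rpn501 may lie on its near-identical copy. The lowest wild-type group mean of rpn501 was 0.728 scaled CPM in Pem2, without an ell1 deletion, as a strain variant at rpn501 would give. The adjacent cox1101 was not low in Pem2 wild type, at 6.15 and 5.91 against 0.211 and 0.449 in ED666b ell1Δ. Pem2 wild type thus matches the fall of rpn501 and not that of the pair. For cox1101 the log2 ratio of the sum with cox1102 was -0.30, so a move of reads to cox1102 does not account for the whole fall. The Pem2 level does not say whether the ED666b ell1Δ strain carries such a variant; this and an effect of the deletion itself both stay open for the pair.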

How the results depend on the processing

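The edgeR test on recovered reads, the list tests with a library left out, and the overlaps and antisense counts with a library left out or a replicate block were chosen only after the results had been seen; the other alternatives were fixed before the data were examined. Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested. A pseudocount of 5 gave 23 in Pem2 ell1Δ. Fitting only the compared groups gave 65 in ebp1Δ, 11 in eaf1Δ, 323 for eaf1Δ against ebp1Δ and 19 for ell1Δ against ebp1Δ effects. In Pem2 limma then gave 0, with 530 at an unadjusted p under 0.05. Using all 5 ED666 wild-type libraries gave 121 in eaf1Δ, 50 in ED666b ell1Δ, 18 for ell1Δ against eaf1Δ effects and 949 for ell1Δ against ebp1Δ effects. By edgeR, fitted over all 17 libraries, the count was 27 in eaf1Δ and 40 in Pem2 ell1Δ. Quantile normalization put the share of rises at 35.6% instead of 25.2% in ebp1Δ and at 67.7% instead of 79.2% for eaf1Δ against ebp1Δ.

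Here a library was left out only for comparisons that include its group. Counts then ran from 134 to 368 in ebp1Δ, 21 to 70 in eaf1Δ, 103 to 152 for eaf1Δ against ebp1Δ and 6 to 9 for ell1Δ against eaf1Δ effects. Other libraries enter a comparison only through the shared spread. Without ED666 wild-type replicate 3, 46 genes rose and 15 fell in ED666b ell1Δ, and 33 and 10 in Pem2 ell1Δ, deleted genes aside. Without ED666 wild-type replicate 2 these were 19 and 2 in ED666b and 8 and 1 in Pem2. Counts moved by over 1.5 times in ebp1Δ without wild-type replicate 3 (368) and ebp1Δ replicates 2 (134) and 3 (141), and in eaf1Δ without eaf1Δ replicates 2 (24) and 3 (21). They did so in ED666b ell1Δ without wild-type replicates 1b (8) and 2b (5) and ell1Δ replicates 1b (6) and 2b (7), and in Pem2 without wild-type replicate 1 (3) and ell1Δ replicates 1 (9) and 2 (3). For eaf1Δ against ebp1Δ these were eaf1Δ replicates 1 (105) and 2 (116) and ebp1Δ replicates 2 (114) and 3 (103), and for ell1Δ against ebp1Δ effects ED666 wild-type replicate 3 (71), ED666b wild-type replicate 1b (22) and ell1Δ replicate 2b (22). Called lists ran from 6 to 10 in ebp1Δ, 6 to 14 in eaf1Δ, 3 to 9 in ED666b ell1Δ and 4 to 11 in Pem2 ell1Δ, with 6 in eaf1Δ without wild-type replicate 3, 3 in ED666b without wild-type replicate 1b, and 4 and 5 in Pem2 without wild-type replicate 1 and ell1Δ replicate 2. The correlation of the ell1Δ effects ran from 0.450, without Pem2 wild-type replicate 1, to 0.626. Direction turned, without wild-type replicate 3, for cytosolic ribosomal proteins in ebp1Δ (limma camera adjusted p = 0.00889, over its alternatives 1.57e-07 to 0.113) and in eaf1Δ for ribosome biogenesis (0.419, over its alternatives 4.65e-10 to 0.419) and purine synthesis (0.508, over its alternatives 2.47e-04 to 0.508). Shared rises ran from 2 to 21 for ebp1Δ and eaf1Δ, 0 to 10 for ebp1Δ and ED666b ell1Δ, 1 to 8 for ebp1Δ and Pem2 ell1Δ, 1 to 25 for eaf1Δ and ED666b ell1Δ, 2 to 16 for eaf1Δ and Pem2 ell1Δ and 2 to 11 for the 2 ell1Δ comparisons. Shared falls ran, in the same order, from 4 to 17, 0 to 5, 0 to 7, 0 to 3, 0 to 2, and stayed at 0. Antisense RNAs ran from 5 to 32 of the rises and 23 to 37 of the falls in ebp1Δ, and from 8 to 30 of the rises in eaf1Δ, 2 to 3 in ED666b ell1Δ and 2 to 10 in Pem2 ell1Δ. Of 36 list calls 15 held under every alternative at the preset correlation, and 0 with an estimated correlation.

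Replicate numbers did not pair the ED666 libraries, where same-numbered libraries had deviations correlated at -0.219 to 0.243, 5 of 9 pairs over 0.1, and 3 of 9 libraries correlated best with their own number. In the ell1Δ sets all 12 same-numbered pairs were over 0.1, so the block is given beside those results. The replicate block raised the count to 340 in ebp1Δ, 91 in eaf1Δ, 28 in Pem2 ell1Δ, 285 for eaf1Δ against ebp1Δ and 91 for ell1Δ against ebp1Δ effects, and it ended the cytosolic ribosomal protein call in ED666b ell1Δ (limma camera adjusted p over its alternatives 3.29e-04 to 0.702). With the block the shared rises were 21 for ebp1Δ and eaf1Δ, 6 for ebp1Δ and ED666b ell1Δ, 4 for ebp1Δ and Pem2 ell1Δ, 22 for eaf1Δ and ED666b ell1Δ, 14 for eaf1Δ and Pem2 ell1Δ and 16 for the ell1Δ comparisons. Shared falls were 28 for ebp1Δ and eaf1Δ, 5 for ebp1Δ and Pem2 ell1Δ, 3 for eaf1Δ and Pem2 ell1Δ and 2 for the ell1Δ comparisons, and 16 antisense RNAs rose in Pem2 ell1Δ. In the ell1Δ comparisons the block changed the calls of agn1 and cfh4 in ED666b, SPNCRNA.1289 and SPNCRNA.1306 in Pem2 and pho84 in both, and, besides these and the ribosomal protein list, no other named gene or list call. In ED666 it ended the calls of mes1 in ebp1Δ and of SPNCRNA.1487, rib7, SPNCRNA.844 and hht1 in eaf1Δ, and mug9 passed in eaf1Δ (limma adjusted p over its alternatives 0.0182 to 0.519).

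For the 135 named gene results, some of them not called, 2259 alternatives left the call or its absence unchanged in 1878 cases. A call was lost in 376 and gained in 5, and the direction turned in 0. The DESeq2 alternative, planned for deposited counts, was left out, and edgeR was the count test run on the recovered reads. Depth limits ED666 most, where 3 reads equalled up to 0.462 scaled CPM.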

Other observations

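The adjacency and culture state tests, the antisense enrichment, the comparisons of length correlations with replicates and with the other background, and the single genes ura4, ftm4 and SPAC750.06c were chosen only after their values had been seen.

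The subtelomeric gene ftm4 fell in eaf1Δ (limma adjusted p = 2.40e-05) and rose in Pem2 ell1Δ (limma adjusted p = 0.00591), and it did not pass in ED666b ell1Δ (limma adjusted p = 0.907). Its level was 0.0372 ± 0.0644 scaled CPM in eaf1Δ, with 1 read over 3 libraries, and 4.57 ± 1.64 in wild type (n = 3 each), against 9.02 ± 1.02 and 6.42 ± 0.252 in ED666b ell1Δ and wild type and 8.41 ± 0.727 and 2.26 ± 0.204 in Pem2 ell1Δ and wild type (n = 2 each). SPAC750.01 was low in the same eaf1Δ libraries. So was SPAC750.06c, at 0, 0 and 0.112 in eaf1Δ against 1.21, 0.892 and 1.84 in ED666 wild type. Whether the falls of these SPAC750 genes follow from the loss of eaf1 itself was not tested. Genes called in ebp1Δ also lay next to each other. Among 218 called genes with a position 29 adjacent pairs were found, where 10000 random draws had a median of 8 and a highest value of 19. Neighbouring genes may thus change together; whether overlapping transcripts counted without strand give such pairs was not tested.

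Antisense-named RNAs rose in eaf1Δ and in both ell1Δ comparisons. If reads of the sense partner had been counted on the antisense gene, the partners should have risen as well, but their median log2 fold change was 0.025 against 1.08 for the antisense RNAs. These are 47 values over 3 comparisons from 30 distinct pairs, and the bootstrap SE of the sense median, resampling distinct pairs, was 0.028. Low genes passing more often does not account for the whole share, since at most 2 of 10000 lists matched on level had as high a share of antisense RNAs in any of the 3 comparisons. The median share of the matched lists was 25% for eaf1Δ, 28% for ED666b ell1Δ and 36.4% for Pem2 ell1Δ, above the 9.23% of all tested genes. A rise of antisense transcription or stability after loss of ELL or EAF remains a hypothesis, found and tested on the same data. The use of strand in counting stays open.

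Whether the fall of 168 genes in ebp1Δ, by a median log2 fold change of -0.78, follows the state of the culture was not decided by these libraries. Over these genes wild-type replicate 2 minus replicate 1 had a median of 0.073 in ED666b and 0.067 in Pem2, both above the range of 95% of 10000 lists matched on level (-0.016 to 0.058 and -0.014 to 0.037), but each value is 1 library minus 1 library, and the same-numbered wild-type libraries of these sets had correlated deviations (r = 0.424). Wild-type ED666 replicate 3, with ght5 at 948 against 129 and 70.8 in replicates 1 and 2, is the ED666 wild-type library nearest to the ebp1Δ level of this gene (1089, 975 and 1031). It did not stand lower as a whole over the genes that fell, where its median log2 difference from the mean of the other 2 wild-type libraries was 0.058, with 72 highest and 45 lowest in it, and abp2 and cnp3 were highest there (141 and 257 scaled CPM). These genes were called with this library among the controls, which works against genes that are low in it. Without it 224 genes fell in ebp1Δ, so the median over the 168 cannot decide the question. A single library excludes nothing, so the culture stays open beside the deletion itself.

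The 6 libraries of each ED666 comparison make 10 splits, so a share under 0.05 cannot be reached. The real split gave 226 genes in ebp1Δ, 52 in eaf1Δ and 183 for eaf1Δ against ebp1Δ, each matched by 1 of 10 splits, the real one, with highest other values of 2, 2 and 0 by limma, where the 183 had 895 genes at an unadjusted p under 0.05. For gene lists 7 were called in ebp1Δ, matched by 6 of 10 splits with 13 the highest other, and 11 in eaf1Δ, matched by 1 with 8 the highest other.

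Whether longer genes fall after loss of an elongation factor was tested by Spearman's rho of log2 fold change and length across 4960 coding genes, which are not independent. It was -0.00561 in ebp1Δ, 0.0328 in eaf1Δ, -0.364 in ED666b ell1Δ and 0.252 in Pem2 ell1Δ. The ED666b value cannot be told apart from library differences, since the other background gave the opposite sign and replicates within a group reached 0.246 in size. The largest change among tested genes next to the deleted ones was 0.39 (SPRRNA.39, ED666b), and no such gene was called by limma in the 4 deletion comparisons (smallest adjusted p = 0.119).

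The uracil gene ura4 stood at 3.60 scaled CPM in eaf1Δ replicate 3 and at 0 in each of the 16 other libraries.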
